A study of Mus musculus with 2 samples.

How the data were processed

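5hmC was measured in 1 Tet2+/+ and 1 Tet2-/- library of sorted mast cells by chemical labelling and biotin pulldown. Per the labels' protocols, 4 µg of genomic DNA per library was sonicated to 200 to 400 bp before enrichment. Bowtie2, an aligner, and MACS2, a peak caller, are named with the mm9 build per the submitters' processing notes. Their versions, thresholds and options are not given in the sources used here. The authors deposited 4 peak lists, 2 per library: peaks of the library alone, and peaks called with the other library as control, as their peak names state. Peaks were called per library. Positions on 8 of 21 chromosomes passed the end of the last gene of the GRCm38 table, which fits mm9 and not GRCm38, so that table was not used to place genes.

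Each deposited peak has a fold enrichment at its summit, a −log10 p, a −log10 q and a score, all made by the authors' peak caller. The deposited score is 10 times the −log10 p, rounded down, for all peaks but 1 in each own list. The lowest −log10 p was between 4.06 and 4.19 in each list. A −log10 q under 2 was found for 233 of the 2724 peaks higher in Tet2+/+ and 51 of the 469 higher in Tet2-/-. Fold, p and q are the authors' values and serve to describe, rank or filter peaks within a list, so medians of different lists are given side by side without a test. Peaks were not masked for repeated sequence, for which no mm9 mask was used here. Start positions were converted from 0-based to 1-based.

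Depth was read from the deposited values. MACS2 sets the fold to the summit pileup plus 1 over the expected pileup plus 1, and p to the Poisson tail of the pileup, so both together give the 2 pileups. A whole number of fragments met the deposited −log10 p within 0.001 for 100% of peaks in each list, and the next best number was over 10 times farther off. In the list of peaks higher in Tet2-/- this held once the Tet2-/- pileup was scaled by 0.848, the ratio of the 2 library backgrounds. Expected pileups above the genome background came in steps of 0.02 in 100% of Tet2+/+ and 99.99% of Tet2-/- own peaks (within 0.01 of a step). This is the share of 1 fragment of 200 bp in a window of 10 kb, so the own lists appear to have been called against the library's own surroundings with no input library. In the direct-comparison lists, 68.8% and 65.6% of expected pileups above background were whole fragments of the other library (within 0.01). The expectation from a control library is not that library's coverage at the summit: at 247 peaks higher in Tet2+/+ whose summit lay within 20 bp of a Tet2-/- summit it was 0.526 of that coverage (median), in regions that were themselves called for a low expectation. The recovery returned 100% of the simulated fragment counts, and the overlap rules returned 100% of the simulated overlaps. The simulated counts followed the same formulas that the recovery inverts, so they check the calculation and not how the deposited values were made.

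Lists were compared by overlap of at least 1 bp with bedtools 2.31.1, and counts, intervals and draws were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Shares have 95% exact Clopper-Pearson intervals, fragment counts have exact Poisson intervals, and a count of 0 allows up to 3 counts of the total. Neighbouring peaks and amplified fragments are not independent, so these intervals and limits cover counting error only. Shuffles placed peaks between the first and last peak of their chromosome, assembly gaps included. Windows of 100 kb counted summits. With 1 library per genotype no test across samples was possible.

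Before the data were examined, the named regions were set as the 10 peaks of highest −log10 q in each direct-comparison list and the 5 windows with the most such peaks, ties by fold for peaks; ties between windows were ordered by the highest −log10 q, which was not set beforehand. Gene lists for mast cells, other blood cells, DNA methylation and the cell cycle had been fixed as well, but they and the annotation of peaks by gene need an mm9 annotation, which was not used here, so neither was analysed. The alternatives tried were stricter q limits, a fold limit, 3 other rules of overlap, lists of equal length, a limit on 1 list only, merged peaks, autosomes alone and larger windows, and, after seeing the data, direct-comparison peaks recomputed at 1 common depth with and without the general shift between the libraries. For the closing section, peaks of the 2 libraries that overlapped with summits within 100 bp were paired, 8441 in all, and their fragments compared by an exact binomial test at the depth ratio, which compares these libraries and not the genotypes. In a simulation of such pairs, 69.5% of those changed 3-fold and 0.0897% of those unchanged passed a binomial p of 0.001.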

Results

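Hydroxymethylation was mapped in mouse bone marrow-derived mast cells, which are primary mast cells grown from bone marrow in interleukin-3. Cells came from Tet2+/+ and Tet2-/- C57BL/6 mice. TET2 is an enzyme that oxidises methylated cytosine in DNA to 5-hydroxymethylcytosine (5hmC). Mast cells were taken after 4 weeks of differentiation by sorting for surface Kit, the stem cell factor receptor, and FcεRIα, a chain of the high-affinity IgE receptor, because knockout cultures differentiated less completely, per the labels. Fragments carrying 5hmC were glucosylated, biotinylated, pulled down and sequenced. There was 1 library per genotype. Cells came from 2 animals per genotype, and the labels do not say whether their DNA was pooled. No replicate spread exists, so no p-value is given for any genotype difference, and intervals cover counting error only. The values are the authors' peak lists: each library's own peaks, and the peaks of each library called with the other library as control. The read totals are unknown, but the peak statistics gave the background of each library, 1.46 expected fragments per position in Tet2+/+ and 1.72 in Tet2-/-, so the Tet2-/- library was 1.18 times as deep. Positions are in the mm9 build. No gene annotation of that build was used, so regions are named by coordinates alone and the targeted gene itself was not examined.

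The first comparison asked how many regions carried enriched 5hmC with and without TET2. Peaks were found in both genotypes in similar number, 18160 in Tet2+/+ cells and 16875 in Tet2-/- cells, a ratio of 1.08 (95% interval 1.05 to 1.10). The Tet2+/+ peaks covered 6.48 Mb and the Tet2-/- peaks 5.76 Mb. Peaks were short, with a median width of 328 bp in Tet2+/+ and 318 bp in Tet2-/-. Median fold enrichment over the library's own surroundings, as the authors' peak caller gave it, was 5.48 in Tet2+/+ and 5.51 in Tet2-/-. The median summit was covered by 17 fragments in Tet2+/+ and 18 in Tet2-/-. On each of the 19 autosomes Tet2+/+ cells had more peaks than Tet2-/- cells. The order of the genotypes turned round among strong peaks: at −log10 q of at least 10 there were 4930 peaks in Tet2+/+ and 5246 in the deeper Tet2-/- library, a ratio of 0.940.

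Most called peaks were common to both libraries. Of the Tet2+/+ peaks, 11107 (61.2%, 95% exact interval 60.4 to 61.9) overlapped a Tet2-/- peak by at least 1 bp, and 11103 of the Tet2-/- peaks (65.8%, 65.1 to 66.5) overlapped a Tet2+/+ peak. When peaks were placed at random within their chromosome 100 times, the mean overlap was 0.496% and 0.540%. The remaining 7053 Tet2+/+ peaks and 5772 Tet2-/- peaks had no partner. Those without a partner were the weaker ones: the median fold was 4.96 for unpartnered and 5.97 for partnered Tet2+/+ peaks, and the median −log10 q was 5.26 and 8.54. Unpartnered Tet2-/- peaks had a median fold of 4.90, against 5.93 for partnered ones. In the strongest quartile of Tet2+/+ peaks 90.0% overlapped a Tet2-/- peak, and in the weakest quartile 37.0%. The shares for Tet2-/- peaks were 91.0% and 43.7%. A missing partner was thus most frequent where a peak lay near the calling threshold. The own lists appear to have been called with no input library, and no mask of repeated sequence was applied. How many of the common peaks reflect repeats and not 5hmC was not tested.

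**Figure D1:**
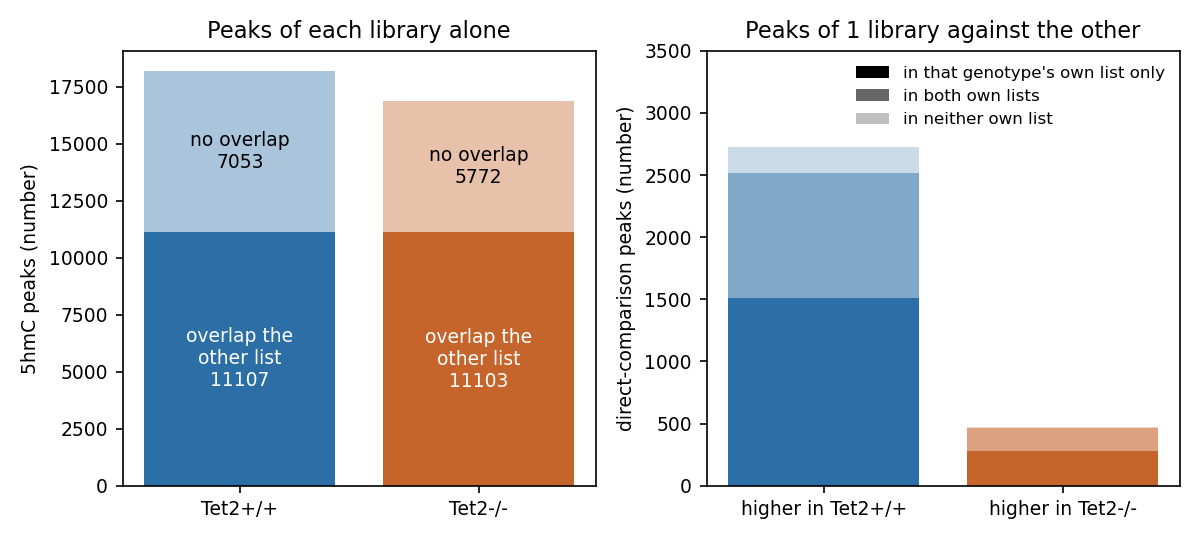
Left, number of 5hmC peaks called in each library alone, divided by whether they overlap a peak of the other genotype by at least 1 bp. Right, number of peaks called in 1 library against the other, divided by the own lists they overlap; 2724 were higher in Tet2+/+ and 469 higher in Tet2-/-.

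**Figure D2:**
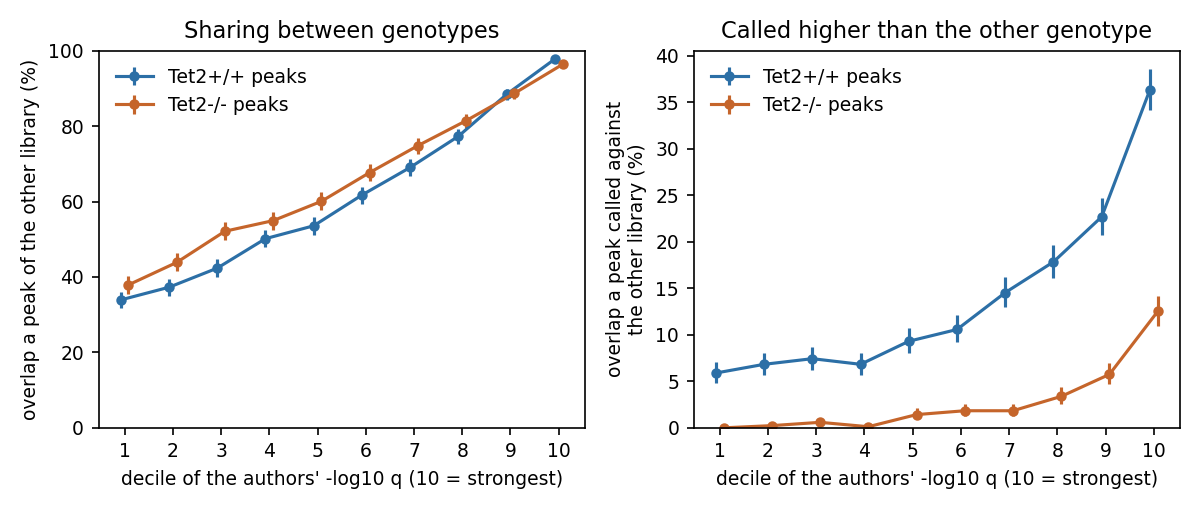
Share of each library's own peaks that overlap a peak of the other library (left) and a peak called against the other library (right), by decile of the authors' −log10 q. Points are shares in percent and bars 95% exact binomial intervals; both shares are highest in the strongest decile, where 97.8% of Tet2+/+ and 96.4% of Tet2-/- peaks had a partner.

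The second comparison asked where the 2 genotypes differed when each library was called directly against the other. Regions higher in Tet2+/+ outnumbered regions higher in Tet2-/- by 5.81 to 1 (95% interval 5.26 to 6.42): 2724 peaks covering 0.737 Mb against 469 peaks covering 0.121 Mb. No region was in both lists. The deposited fold had a median of 4.04 (interquartile range 3.34 to 4.80) among peaks higher in Tet2+/+ and of 3.93 (3.31 to 4.70) among peaks higher in Tet2-/-. On each of the 19 autosomes more peaks were higher in Tet2+/+ than in Tet2-/-. The count ratio depended on the limit of significance and on scaling. Among peaks with −log10 p of at least 10, at the common depth that the deposited calls already used, it was 4.45. It fell to 1.79 (601 against 335 peaks, 95% interval 1.57 to 2.06) when a general difference of 0.19 (log2) between the libraries at their common peaks was removed. Both of these settings were chosen after seeing the data. The deposited folds also exceed the difference in coverage: at 805 pairs of own peaks with summits within 100 bp whose Tet2+/+ peak overlapped a region higher in Tet2+/+, Tet2+/+ coverage was a median of 1.87 times the depth-scaled Tet2-/- coverage, against a median deposited fold of 3.34.

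Regions higher in Tet2+/+ were for the most part regions already called in Tet2+/+ alone. Of the 2724, 1514 (55.6%) overlapped a peak in the Tet2+/+ list but none in the Tet2-/- list, 1004 (36.9%) overlapped a peak in both, and 206 (7.56%) overlapped neither. None overlapped a Tet2-/- peak only (0 of 2724, which allows a share of up to 0.110%). So over 1 in 3 regions higher in Tet2+/+ still overlapped a called 5hmC peak in Tet2-/- cells by at least 1 bp. With reciprocal overlap of at least 50% the share was 27.0% (25.3 to 28.7). Of the regions higher in Tet2-/-, 280 (59.7%) were in the Tet2-/- list alone and 187 (39.9%) in both lists. Only 2 (0.426%, 95% exact interval 0.0517 to 1.53) were in neither list, a lower share than among regions higher in Tet2+/+ (6.60 to 8.62). The 2 shares are not on the same footing, since the Tet2-/- pileup was scaled down in the direct call but not in its own list. Regions higher in Tet2-/- had a median of 30 fragments, against 21 in those higher in Tet2+/+. Absence of a peak in the other genotype did not by itself carry over to a direct call. Of the 7053 Tet2+/+ peaks without a Tet2-/- partner, 1492 (21.2%, 95% exact interval 20.2 to 22.1) overlapped a peak called higher in Tet2+/+, and 5561 did not. Among partnered Tet2+/+ peaks the share was 9.17% (8.64 to 9.73). Of the 5772 Tet2-/- peaks without a partner, 279 (4.83%, 4.29 to 5.42) overlapped a peak called higher in Tet2-/-. Direct calls were most frequent at strong peaks, 27.6% of the strongest quartile of Tet2+/+ peaks against 6.70% of the weakest, and 7.97% against 0.190% for Tet2-/- peaks. A direct call needs enough fragments to reach its p, so weak peaks are harder to call at the same fold. These shares therefore do not show that the libraries differed more at strong peaks.

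The region of highest significance among those higher in Tet2+/+ lay on chromosome 5 at 75782571 to 75782924, where 76 Tet2+/+ fragments (95% Poisson interval 59.9 to 95.1) covered the summit. The peak caller expected 12.7 from the Tet2-/- library, and the overlapping peak of the Tet2-/- library itself had 31 fragments, or 26.3 at the depth of Tet2+/+. A second region on chromosome 5, at 35145295 to 35145651, had 81 fragments in Tet2+/+ and 38 in the Tet2-/- peak. In 5 of the 10 leading regions the Tet2-/- library had no called peak. These were chromosome 13 at 56405585 to 56405940 (37 Tet2+/+ fragments, 2.54 expected), chromosome 15 at 94224720 to 94225338 (36 fragments, 2.54 expected), chromosome 10 at 117005479 to 117005910 (29 fragments, 1.46 expected), chromosome 12 at 25712397 to 25712909 (41 fragments, 4.24 expected) and chromosome 19 at 21541202 to 21541797 (31 fragments, 2.37 expected). The other leading regions, on chromosome 11 at 72694219 to 72694497, chromosome 1 at 93478807 to 93479194 and chromosome 7 at 147155673 to 147155958, had 77, 46 and 64 Tet2+/+ fragments over peaks of 52, 18 and 32 fragments in Tet2-/-. Deposited folds of the 10 regions ran from 4.56 to 12.2. Where both libraries had a peak, depth-scaled coverage was 1.75 to 3.01 times as high in Tet2+/+.

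Among regions higher in Tet2-/-, the leading one lay on chromosome 12 at 105997693 to 105998059, with 88 Tet2-/- fragments (95% Poisson interval 70.6 to 108) over a Tet2+/+ peak of 18 fragments, 4.15 times as high after scaling for depth. Next came chromosome 13 at 85399023 to 85399349, with 83 Tet2-/- fragments over a Tet2+/+ peak of 28. Tet2+/+ cells had no called peak at chromosome 1, 196915262 to 196915624 (46 Tet2-/- fragments, 3.54 expected), and at chromosome 1, 35926143 to 35926567 (52 fragments, 7.08 expected). The other 8 of the 10 leading regions held a peak in both libraries, with depth-scaled coverage 1.36 to 4.15 times as high in Tet2-/-. The smallest of these differences was at chromosome 12, 112482853 to 112483096, where 112 Tet2-/- fragments stood over a Tet2+/+ peak of 70.

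**Figure D3:**
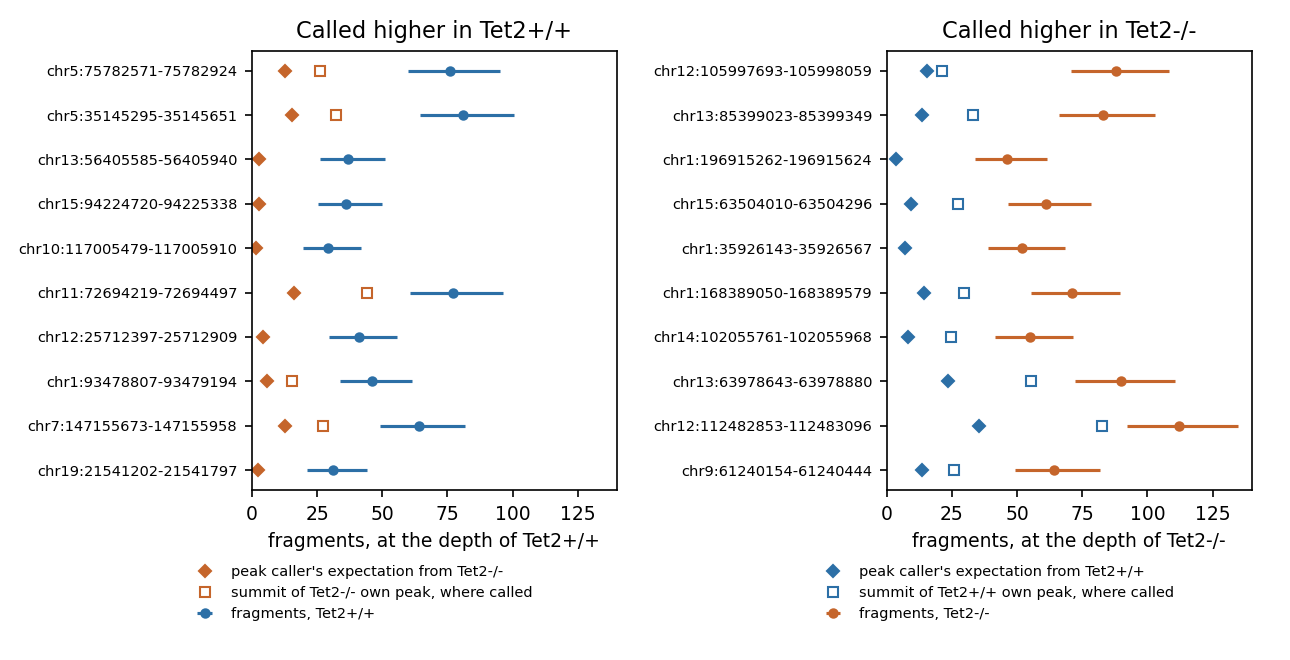
The 10 regions of highest −log10 q called higher in Tet2+/+ (left) and in Tet2-/- (right), by mm9 position. Circles are fragments over the summit with 95% Poisson intervals, diamonds the peak caller's expectation from the other library and open squares the summit of the other library's own peak where one was called, all at the depth of the higher library; squares lie to the right of the diamonds in all 13 regions that have both.

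The third comparison asked whether the difference was spread over the genome. The share of Tet2+/+ peaks that overlapped a peak called higher in Tet2+/+ was 13.9% on the autosomes together (95% exact interval 13.4 to 14.5), between 10.9% on chromosome 14 and 17.5% on chromosome 17. Among autosomes, chromosome 17 also had the lowest share of Tet2-/- peaks called higher in Tet2-/-, 1.75%, and chromosome 14 the highest, 4.35%. The shares were 1.25% on X (3 of 240 peaks, 0.259 to 3.61) and 1.11% on Y (1 of 90 peaks, 0.0281 to 6.04). Both intervals include the 2.80% of the autosomes together. Chromosome X carried few peaks and showed a share of 9.41% (5.76 to 14.3), whose interval includes the autosomal value. At −log10 q of at least 5 the X share was 2.48% (0.681 to 6.24), which excludes the autosomal 7.91% (7.45 to 8.38), but at −log10 q of at least 10 it was 0 of 40 peaks, which allows up to 7.50% and so includes the autosomal 2.99%. On chromosome Y none of 76 Tet2+/+ peaks was called higher, which allows a share of up to 3.95%. The ratio of Tet2-/- to Tet2+/+ peaks was 0.925 (0.906 to 0.945) on the autosomes and 1.19 (0.981 to 1.44) on X, with 202 peaks in Tet2+/+ and 240 in Tet2-/-. On Y, with 76 and 90 peaks, it was 1.18 (0.863 to 1.63), which does not separate it from the autosomes.

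**Figure D4:**
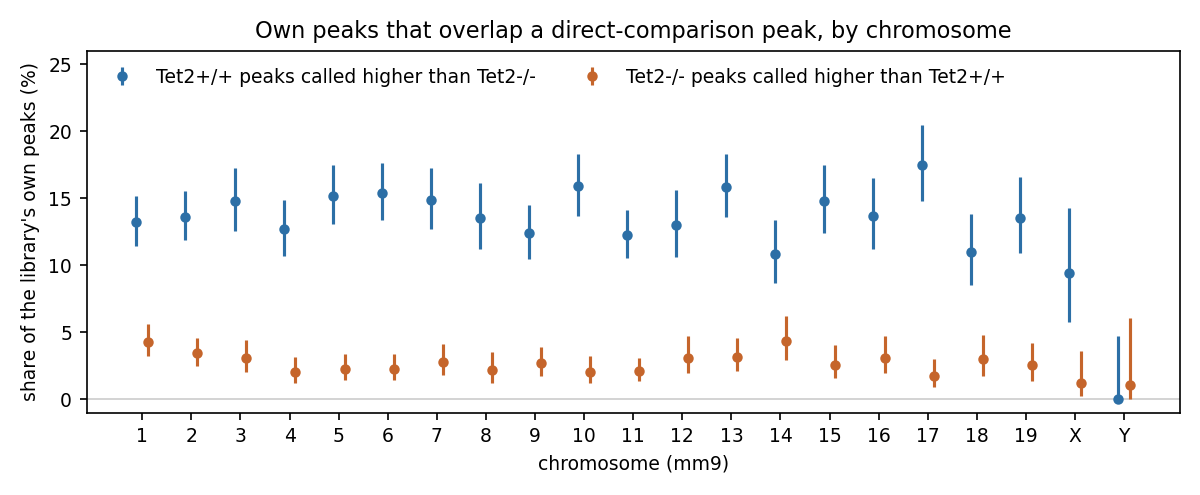
Share of each library's own peaks that overlap a peak called higher than in the other genotype, in percent, by mm9 chromosome. Points are shares and bars 95% exact binomial intervals; the Tet2+/+ share lies above the Tet2-/- share on each of the 19 autosomes.

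Regions higher in Tet2+/+ were locally concentrated. The fullest window of 100 kb, on chromosome 15 from 58.8 to 58.9 Mb, held 7 of them, beside 10 Tet2+/+ and 12 Tet2-/- own peaks and 1 region higher in Tet2-/-. Windows with 6 such regions lay on chromosome 17 from 7.3 to 7.4 Mb, on chromosome 16 from 93.2 to 93.3 Mb and from 92.7 to 92.8 Mb, and on chromosome 2 from 104.3 to 104.4 Mb. The chromosome 2 window had 5 Tet2+/+ own peaks and none in Tet2-/-. The chromosome 16 windows had 11 and 13 Tet2+/+ own peaks and 7 Tet2-/- own peaks each. When 2724 peaks were drawn at random from the Tet2+/+ list, the fullest window reached 7 or more in 2 of 100 draws. Draws for windows were not matched on fragments in either list, although direct calls lay mostly at strong peaks. The 206 regions outside the Tet2+/+ list could not be drawn. Regions higher in Tet2-/- reached 4 in a window on chromosome 14 from 70.0 to 70.1 Mb, which 1 of 100 draws from the Tet2-/- list equalled, and 3 on chromosome 1 from 108.5 to 108.6 Mb. In windows of 1 Mb, regions higher in Tet2+/+ reached 14, as in 2 of 100 draws, while regions higher in Tet2-/- reached 4, which 75 of 100 draws equalled or passed. A window of 100 kb with 2 regions higher in Tet2-/- does not stand out, since the fullest window of every draw held at least 2, and 2.33 on average. How many such windows the draws held was not compared.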

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

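The settings at −log10 p of at least 10 were chosen after seeing the data. Over 20 results and 14 alternative settings, 97 values were recomputed: 32 stayed within their counting interval or, for counts, within 1.5 times, 64 moved farther, and 1 reversed. The excess of regions called higher in Tet2+/+ held in every setting run, with a ratio from 1.75 to 6.13. Merging peaks within 1000 bp and leaving out X and Y left the numbers of peaks and their ratios within those limits. With −log10 q of at least 5, the ratio of own peaks was 1.05, and 60.1% of Tet2+/+ and 63.2% of Tet2-/- peaks overlapped the other list. There were then 1071 regions higher in Tet2+/+, 97.4% of them in the Tet2+/+ list and 43.0% in the Tet2-/- list, and 191 higher in Tet2-/-, 100% of them in the Tet2-/- list. In the strongest and weakest quartiles of Tet2-/- peaks the overlap was 89.2% and 40.3%. The share of Tet2+/+ peaks called higher was 7.91% on autosomes and 2.48% on X, whose interval then excluded the autosomal share. With −log10 q of at least 10, Tet2+/+ had 4930 own peaks and Tet2-/- 5246, which reversed the ratio to 0.940, and the cause was not tested. Overlap was then 58.5% for Tet2+/+ and 55.0% for Tet2-/- peaks, 85.8% in the strongest quartile of Tet2+/+ peaks, and 83.8% and 32.6% in the strongest and weakest quartiles of Tet2-/- peaks. Regions higher in Tet2+/+ numbered 147 (98.6% in the Tet2+/+ list) and those higher in Tet2-/- 31 (100% in the Tet2-/- and 29.0% in the Tet2+/+ list), a ratio of 4.74. The share called higher was 2.99% on autosomes and 0 on X, which allows up to 7.50% and no longer separated them. Fewer peaks at stricter limits follow from the limits themselves. With reciprocal overlap of at least 50%, overlap was 53.9% for Tet2+/+ and 58.0% for Tet2-/- peaks, with 85.2% and 27.4% in the strongest and weakest quartiles of Tet2+/+ peaks and 87.0% and 33.1% in those of Tet2-/- peaks. Regions higher in Tet2+/+ were in the Tet2+/+ list in 73.1% and in the Tet2-/- list in 27.0% of cases, and regions higher in Tet2-/- were in the Tet2-/- list in 71.4% and in the Tet2+/+ list in 24.5%. With the summit inside the other peak, overlap was 59.6% and 64.2%, and in the weakest quartile it was 33.5% for Tet2+/+ and 41.1% for Tet2-/- peaks. Counting peaks within 1000 bp as shared gave 64.1% and 68.9%, with 42.4% of Tet2+/+ and 48.5% of Tet2-/- peaks in the weakest quartile and 92.2% of Tet2-/- peaks in the strongest. Regions higher in Tet2+/+ were then in the Tet2+/+ list in 93.5% and in the Tet2-/- list in 42.1% of cases, and regions higher in Tet2-/- in the Tet2+/+ list in 46.3%. Lists of equal length overlapped by 63.26% and 63.32%, and a −log10 q of at least 5 in the first list alone gave 69.8% and 73.1%. A fold of at least 5 left 11819 Tet2+/+ and 11023 Tet2-/- own peaks, and 509 and 83 regions higher in each. At −log10 p of at least 10 and the common depth of the deposited calls, the ratio of regions was 4.45. With the general shift removed as well it was 1.79, or 1.75 when the shift was taken from autosomes alone. The shifts under the other overlap rules follow from how strict each rule is, and other causes were not tested. Alternatives for the annotation of peaks and for gene lists were not run, since both need an mm9 annotation that was not used here. No paired analysis was possible because each genotype has 1 library. Depth limits single regions: the median own peak rests on 17 Tet2+/+ or 18 Tet2-/- fragments. Of simulated 3-fold changes, 69.5% were found at a binomial p of 0.001, in pairs with more fragments on average than most real pairs.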

Other observations

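The tests chosen only after their result, or a related one, had been seen were those on the strongest direct-comparison peaks with the shift removed, on the expectation against coverage, on chromosomes X and Y, and on neighbours of peaks in both direct-comparison lists. All 10 own peaks of highest −log10 q in each genotype overlapped a peak of the other, and 9 of them were also among the other's 10 strongest. The strongest peak, on chromosome 9 at 35112688 to 35113225, had 231 fragments in Tet2+/+ and 251 in Tet2-/-. A strong peak on chromosome 17 at 36621488 to 36622015 had 96 fragments in Tet2+/+ and 151 in Tet2-/-. No mask of repeated sequence was applied, so whether these strongest peaks reflect 5hmC or repeats was not tested.

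After scaling for depth, most common peaks were slightly higher in Tet2+/+. At 8441 pairs of own peaks with summits within 100 bp, the median log2 ratio of Tet2+/+ to Tet2-/- fragments, scaled for depth, was 0.19 (interquartile range −0.12 to 0.52), and 66.0% of pairs were above 0. By quartile of fragments, the ratio was 0.24 for the pairs with the fewest fragments and 0.13 for those with the most. Equal fragment counts in the 2 libraries also give 0.24 after depth scaling. Pairs had to be called in both libraries, with no fewer than 8 fragments in each. How far this selection shaped the median of 0.19, which served as the general shift, was not tested. At 7144 autosomal pairs with a local background above the genome background in both libraries, the summits had a median of 0.17. The surrounding 10 kb, without the fragments over the summit, had a median of 0.19. Other fragments of the peak and of neighbouring peaks stayed in the surroundings. Before any further scaling, 66 pairs were higher in Tet2+/+ and 7 higher in Tet2-/- at a binomial p under 0.001. In the simulation 0.0897% of unchanged pairs also passed this limit, so the 7 pairs alone do not show gains in Tet2-/-.

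The 5.81-fold excess of regions called higher in Tet2+/+ was weighed against the peak caller's down-scaling of the deeper library and against pulldown efficiency. Down-scaling and rounding by the caller was not settled. With the Tet2+/+ pileup scaled and rounded down as the Tet2-/- pileup had been, the summits of 2620 of the 2724 regions still passed. The bound was the lowest −log10 p of the list higher in Tet2-/-, 4.12, and called regions were at least 200 bp wide. Whether regions would keep that width, and which Tet2-/- regions an unscaled call would add, was not tested, so this decides nothing. A general difference between the libraries, such as a larger share of reads in enriched regions of the Tet2+/+ library, stays open: with the shift of 0.19 removed the differing pairs divided into 25 and 31 (44.6% higher in Tet2+/+, 95% exact interval 31.3 to 58.5), but the shift was the median of the same pairs, which favours an even split and decides nothing. Among the strongest direct-comparison peaks 64.2% (61.0 to 67.3) were higher in Tet2+/+ after that removal. At this shift the interval lies above an even split but includes the bound of 2 in 3 set for the test. The interval takes the shift as exact, although it came only from pairs called in both libraries, so an even split is not excluded. For these peaks the explanation therefore cannot be told apart from a local loss. A genome-wide lower 5hmC content without TET2 could give a like shift to a less efficient pulldown. It stays open and untested, since there was 1 library per genotype and no added standard was used here. At the 7144 autosomal pairs given above the median was 0.17 at summits and 0.19 in the surrounding 10 kb. Those surroundings still held other fragments of peaks, so these values do not show whether the shift reached beyond peaks.

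The fold values of the direct comparison exceeded the difference in coverage at paired own peaks. In those pairs each library's coverage was taken at its own summit, within 100 bp of the other, so the positions compared can differ. At summits within 20 bp of each other the expectation was 0.526 of the Tet2-/- coverage (bootstrap interval 0.505 to 0.538) for regions higher in Tet2+/+, and 0.524 (0.500 to 0.550) of the Tet2+/+ coverage for regions higher in Tet2-/-. The 805 pairs that overlapped a region called higher in Tet2+/+, and were chosen by that call, had a median ratio of 1.87 in the libraries' own coverage, and 66 of them (8.20%) passed a binomial p of 0.001. The 138 pairs in regions called higher in Tet2-/- had a median ratio of 1.82, and 7 passed. Expectations exist only for regions called for a low one, so the way the caller builds its control pileup, not given in the sources used here, cannot be told apart from this selection, and no biological explanation was tested.

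Chromosomes X and Y departed from the autosomes at paired peaks, with a log2 ratio of −0.00 on X (101 pairs) and −0.32 on Y (56 pairs) against 0.20 on autosomes. Animals of different sexes in the 2 libraries would move X and Y in opposite directions, but Y pairs lay below autosomal pairs by a log2 difference of −0.52 (−0.60 to −0.44) and X pairs also lay below them. Counting error on few pairs is argued against by the X difference of −0.20 (−0.30 to −0.07), though neighbouring pairs are not independent. Differences between the animals other than sex, and repeated sequence on Y, may contribute and stay open and untested.

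Regions called higher in Tet2+/+ lay closer together than Tet2+/+ own peaks matched on fragments. Of these regions, 15.9% (14.6 to 17.4) had another within 10 kb, against a mean of 9.88% and a highest of 12.2% in 1000 draws. The 206 regions (7.56%) outside the Tet2+/+ list could not be drawn, and how far they raised the share was not tested. Changes over neighbourhoods, in 5hmC or in read recovery, may underlie the closeness and were not tested. The hypothesis that 5hmC moved between neighbouring sites was neither borne out nor excluded. Of the regions higher in Tet2-/-, 27.9% (23.9 to 32.2) lay within 50 kb of a region higher in Tet2+/+, against a mean of 28.6% (range 22.8 to 36.2) in draws of Tet2-/- peaks that overlapped no such region, and 646 of 1000 draws were at least as high.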
